A study of Homo sapiens with 6 samples.

How the data were processed

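RNA was measured by sequencing in primary human hepatic stellate cells, the liver pericytes that become matrix-producing myofibroblasts when activated, bought from ScienCell and grown for up to 8 passages, per the labels' protocols. The cells received 10 ng/mL platelet-derived growth factor (PDGF) alone or together with 10 µM SHP099, an allosteric inhibitor of the phosphatase SHP2, for 48 hours. Total RNA was extracted with a column kit (RNeasy), per the labels' protocols, and 3 libraries were sequenced per group. Groups and replicate numbers were taken from the sample titles.

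Per the submitters' processing notes, TopHat2 2.1.0, featureCounts and edgeR were used with the GRCh38 (hg38) build, without their options; the library kit and whether strand was used in counting are not given in the sources used here. The deposited count table held raw whole-number counts of 64253 genes for the 6 libraries, with no normalization by the authors. A second table deposited by the authors held RPKM values, scaled to gene length and library size, which were used here only to read the sign of the comparison. The same table gave the authors' log2 fold changes and log2 CPM, and their p-values and false discovery rates over every gene listed, unexpressed genes included.

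Of the gene identifiers, 56591 were found in GENCODE 29, and 52945 of these had the same chromosome, start and end there. Coordinates are those of the deposited table, on GRCh38, counted from 1. Genes on alternative haplotypes or patches numbered 3974 and held 0 counts. A symbol carried by more than 1 gene occurred 1485 times, so genes were followed by identifier. Overlaps between exons of different genes were found with bedtools 2.31.1. Reads of a gene and of an overlapping or antisense partner, or of close relatives such as the CYP3A and CXCL genes and nuclear copies of mitochondrial genes, cannot be told apart here, and those values are uncertain to that extent.

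Library totals were 64145023, 60415856 and 61557053 counts for PDGF replicates 1 to 3 and 63081918, 67971150 and 51925637 for SHP099 replicates 1 to 3. A count of 3 in a library corresponds to between 0.0441 and 0.0578 CPM, and a gene at lower levels may give no count. This covers counting error alone. The filter on low counts left some genes above that level untested. No libraries of a group agreed within sampling noise. The chi-square per degree of freedom was 171 and 163 for PDGF replicate 1 against replicates 2 and 3 and 5.12 between replicates 2 and 3; for SHP099 it was 142, 112 and 10.3.

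The main test was edgeR's quasi-likelihood F-test (edgeR 4.0.16 in R 4.3.3; robust glmQLFit, TMM normalization, default filterByExpr) on the deposited counts with treatment as the only term. It was applied to 21252 genes, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are SHP099 with PDGF over PDGF. CPM values are TMM-normalised means ± SD over 3 libraries, and log2 CPM used a prior count of 2. Library totals alone scaled the CPM behind the numbers of markers under 1 CPM, the highest marker levels and the means given to weigh immune cells. Standard errors were obtained from the fold change and its F statistic. Nothing in the labels says that replicates came from separate cultures or donors, so p-values measure the spread between these samples, which may be technical.

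There were 26 gene lists with 737 members, and 23 of them had at least 5 tested members. These were tested with limma 3.58.1 (camera, preset inter-gene correlation 0.01, two-sided), adjusted over the lists tested; camera with an estimated correlation, camera with ranks and fry, which asks whether a list's genes move one way on balance without comparing them with other genes, were alternatives. The lists covered the PDGF receptor, SHP2 and RAS pathway; ERK pathway output; receptor tyrosine kinases and ligands; interferon-stimulated genes; inflammatory cytokines and chemokines; DNA replication; mitosis; CDK inhibitors and p53 targets; contractile genes; collagens and matrix; matrix metalloproteinases; quiescent stellate cell genes; TGF-beta and BMP signalling; cholesterol and fatty acid synthesis; glycolysis and hypoxia; ATF4 targets; mitochondrial mRNAs; autophagy and lysosome; mTORC1; and extracellular vesicles. The last 6 held markers of hepatocytes, endothelium, macrophages, cholangiocytes, lymphocytes and portal fibroblasts.

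Groups, lists, tests, other settings to be tried and the rule for named genes were fixed before the data were examined. The rule named PTPN11, PDGFRB, PDGFRA, DDIT4, ROCK1, ACTA2, COL1A1 and MKI67 in every case. It added the 8 largest rises and 8 largest falls among genes that passed with an average log2 CPM of at least 2, a gene symbol that is not a clone name and no overlap between groups. Per list it named up to 3 passing members with the smallest p in the direction more members moved and 1 against it, or the member with the smallest p where none passed. Genes of the Y chromosome and XIST were left out of all named results because the cells are from human donors.

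The alternatives fixed in advance were DESeq2's size factors, upper-quartile scaling, library size alone, no filter, an average CPM of at least 1, DESeq2 1.42.0, limma-voom, replicate number as a block, leaving out each library, an adjusted p under 0.01 and a test against a fold of 1.5 (glmTreat). Chosen after seeing the data were the use of replicates 2 and 3 only, a term for replicate 1 against the others, and a correction for GC content with and without the block. The GC correction used as offset each library's lowess trend (span 0.3) of log2 CPM on the GC percent of the longest GENCODE 29 transcript, a value that 97.4% of tested genes had.

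Replicate numbers were checked for pairing by correlating deviations from the group means across genes. Libraries of the same number had correlations of 0.46, 0.27 and 0.23, all over 0.1, and by that rule the numbers were used as pairs. This comes from the data and from no label. PDGF replicate 3 correlated best with SHP099 replicate 2, at 0.29, and PDGF replicate 2 had 0.18 with SHP099 replicate 3. The correlations therefore set replicate 1 apart in both groups but do not show that replicates 2 and 3 are paired by number. For those, the block and the values per same-numbered pair rest on the number alone.

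The fit was tested on simulated data with 200 changed genes and the means and sizes of the real libraries. The changed genes were drawn only from genes above a minimum mean count. The real libraries gave more calls, 1252, so the simulated shares may not carry over to them. Without replicate effects, the unblocked test recovered 5.97%, 62.7% and 97.0% of genes changed 1.5, 2 and 4 fold among 20859 tested, with 9 false calls in 119, and the blocked fit had 26 in 138. With the replicate effects of the real libraries it recovered 2.99%, 41.8% and 78.8% among 20880, with 0 false calls in 82, and the blocked fit recovered 53.7%, 85.1% and 98.5% with 30 false calls in 188. Only the unblocked test with replicate effects kept its share of false calls within the 5% aimed at. In counts simulated with a GC trend, the correction brought the correlation of unchanged genes with GC from −0.56 to −0.0043, recovery of 4-fold changes went from 96% to 94%, and false calls went from 35 of 227 to 19 of 207, both shares above 5%. Scripts also used Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.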

Results

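The series asked how inhibition of SHP2 alters the transcriptome of hepatic stellate cells under PDGF. SHP2, encoded by PTPN11, is a tyrosine phosphatase that relays signals from receptor tyrosine kinases such as the PDGF receptors to RAS and ERK. Cells exposed to 10 ng/mL PDGF for 48 hours were compared with cells exposed to PDGF and 10 µM SHP099, with 3 libraries per group. Every mean below is over n = 3 libraries, with its SD. Library totals lay between 51925637 and 67971150 counts, between 28962 and 30048 genes had at least 1 count, and the 10 most abundant genes took 6.97% to 7.57% of counts.

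With SHP099, 572 genes rose and 680 fell among 21252 tested (edgeR quasi-likelihood, adjusted p under 0.05), with a median absolute log2 fold change of 0.81. At least a 2-fold change was reached by 239 of the genes that rose and 260 of those that fell. The drug target itself did not pass: PTPN11 (ENSG00000179295, chromosome 12, 112418351 to 112509913) averaged 246 ± 29.8 CPM with PDGF and 246 ± 2.90 with SHP099, a log2 fold change of −0.00 (SE 0.11, adjusted p = 0.998). The collagen gene COL1A1 averaged 12668 and 12293 CPM (log2 fold change −0.04, adjusted p = 0.918), the alpha smooth muscle actin gene ACTA2 84.9 ± 3.96 and 106 ± 21.2 CPM (0.32, adjusted p = 0.260), and the proliferation marker MKI67 1.05 ± 0.227 and 1.73 ± 0.633 CPM (0.71, adjusted p = 0.217). ACTA2 passed as higher without SHP099 replicate 1 (0.47, edgeR adjusted p = 0.0303). It also passed with replicates 2 and 3 alone (0.48, edgeR adjusted p = 3.35e-05), a fit that called 8624 of 21260 genes. Its log2 difference between the replicate 1 libraries was −0.07. COL1A1 was at 0.17 with the GC correction (edgeR adjusted p = 0.721). Groups did not overlap for 6381 genes, or 30.03%, where chance gives 10%. With replicate number as a block, 3753 genes passed, 1719 higher and 2034 lower. The count fell to 142 without PDGF replicate 2, 131 without PDGF replicate 3, 180 without SHP099 replicate 2 and 85 without SHP099 replicate 3, and was 2661 without PDGF replicate 1.

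Libraries separated by treatment along the first principal component, which held 44.5% of the variance, and replicate 1 of each group lay apart from replicates 2 and 3 along the second, with 30.6%. With treatment in the model, 4712 genes differed between replicate 1 and replicates 2 and 3. Of these, 2304 were higher and 2408 lower in replicate 1. Fold changes with SHP099 also fell with GC content: over 11408 protein-coding genes the Spearman correlation of log2 fold change with GC percent was −0.42 across genes, which are not independent replicates. The median GC content was 44.8% among genes that rose, 57.6% among genes that fell and 48.5% among all tested genes. With a GC correction, 417 genes were higher and 377 lower, and 697 of the 1252 calls were kept. With replicates 2 and 3 alone, 4148 genes were higher and 4476 lower among 21260 tested. That fit rests on the small spread between those replicates (chi-square per degree of freedom 5.12 and 10.3), so its calls are common. These alternatives were chosen after seeing the data.

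**Figure D1:**
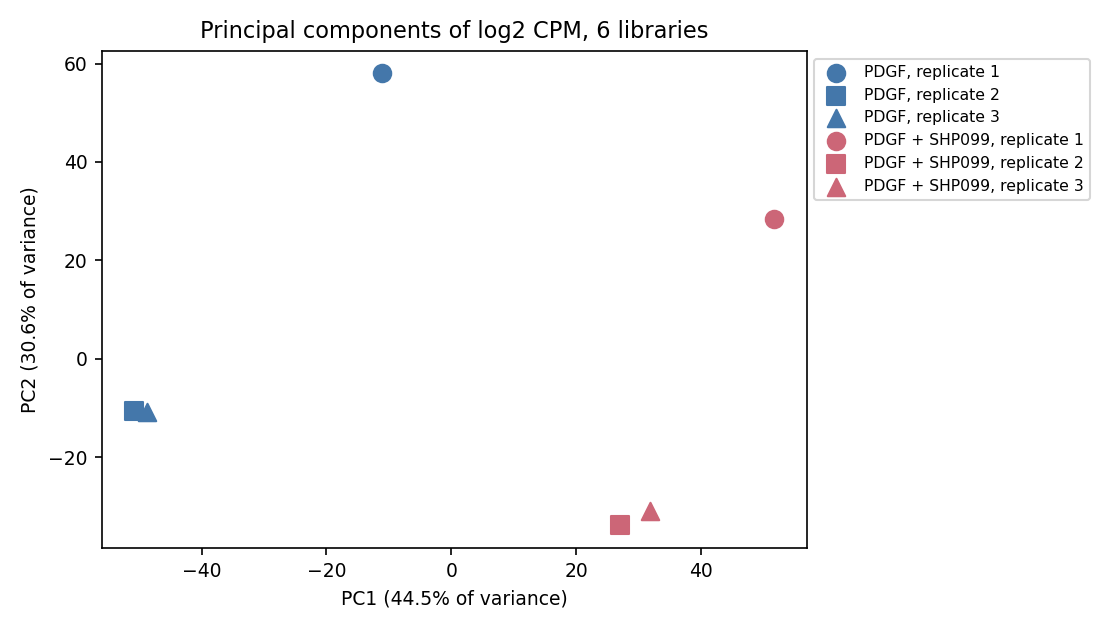
Principal components 1 and 2 of log2 CPM in the 6 libraries, with the percentage of variance on each axis; colour gives the group and shape the replicate number. PDGF libraries lie at negative and SHP099 libraries at positive values of the first component (44.5%), and both replicate 1 libraries lie at positive values of the second (30.6%).

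Changes were ranked among genes that passed with an average log2 CPM of at least 2 and no overlap between groups. The largest fall of these was that of AREG (ENSG00000109321, chromosome 4, 74445134 to 74455009), which encodes amphiregulin, a ligand of the EGF receptor; it went from 112 ± 65.4 to 5.71 ± 1.23 CPM (log2 fold change −4.29, SE 0.45, adjusted p = 0.00657). EREG (ENSG00000124882, chromosome 4, 74365143 to 74388751), for epiregulin, another ligand of that receptor, fell from 86.5 ± 17.1 to 11.9 ± 2.997 CPM (−2.86, SE 0.23). NPTX1 (ENSG00000171246, chromosome 17, 80467148 to 80477843), a neuronal pentraxin, fell from 177 ± 27.04 to 14.3 ± 4.25 CPM (−3.63, SE 0.24, adjusted p = 0.00305). The spindle orientation adaptor INSC fell (−2.93), as did the synaptotagmin-like gene SYTL5 (−3.05), the matrilin gene MATN3 (−3.05), the lipoprotein lipase inhibitor ANGPTL4 (−2.94) and the adhesion molecule L1CAM (−2.90). The largest rise of these was that of CYP3A7 (ENSG00000160870, chromosome 7, 99684679 to 99735196), a cytochrome P450 of fetal liver, from 0.882 ± 0.198 to 9.43 ± 1.99 CPM (3.41, SE 0.24, adjusted p = 0.00321), a value uncertain because of its close CYP3A relatives. The guidance cue NTN1 rose from 2.06 ± 1.06 to 21.4 ± 15.1 CPM (3.37, SE 0.59), the semaphorin receptor PLXNC1 from 2.17 ± 0.792 to 20.03 ± 3.09 CPM (3.20) and TMTC2 from 1.51 ± 0.733 to 14.6 ± 0.302 CPM (3.27). The chemokine CXCL2 (3.11, uncertain because of its close CXCL relatives), the antiviral enzyme OAS2 (2.94), the elastic fibre protein ELN (2.92) and the glycoprotein GPNMB (2.91, SE 0.19) completed the 8 rises within these limits.

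Of the 62 named genes that passed, 16 also passed in every alternative at the same threshold apart from glmTreat, whose calls were not followed for named genes. All 62 kept their direction in each alternative that tested them. The 16 were CYP3A7, TMTC2, PLXNC1, OAS2, ELN, GPNMB, NPTX1, INSC, EREG, LUM, P4HA3, ADIRF, RSAD2, BST2, ID2 and SOX9. The number that still passed was 21 without PDGF replicate 2, 20 without PDGF replicate 3, 51 without SHP099 replicate 1, 23 without SHP099 replicate 2, 16 without SHP099 replicate 3 and 62 without PDGF replicate 1. AREG had an adjusted p of 0.0526 without SHP099 replicate 3 and passed in every other of these fits. The number was 46 with the GC correction, 53 without a filter, 58 with limma-voom, 59 with library size alone and 60 at an average CPM of at least 1. Of the 16 that lost their calls with the GC correction, 14 had a smaller fold and 9 a larger SE. The largest unadjusted p that passed went from 0.00295 to 0.00187, and 8 of the 16 would have passed at the former. With the correction CXCL2 went from 3.11 (SE 0.67) to 3.08 (SE 0.70, adjusted p = 0.0644) and L1CAM from −2.90 (SE 0.62) to −2.70 (SE 0.63, adjusted p = 0.0699), both with a larger SE. Neither passed without a filter (0.198 and 0.189).

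**Figure D2:**
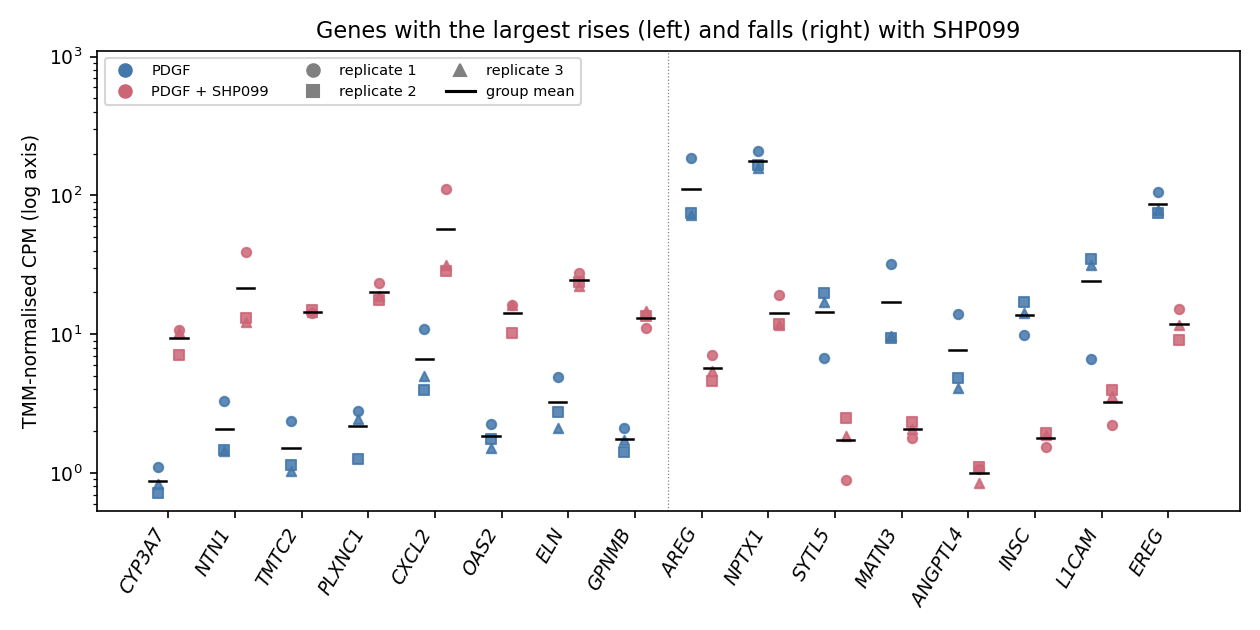
TMM-normalised CPM (log axis) of the 8 genes with the largest rises and the 8 with the largest falls among those that passed with an average log2 CPM of at least 2 and no overlap between groups, for each of the 6 libraries; bars mark group means. All 3 SHP099 libraries lie above all 3 PDGF libraries for the rises and below them for the falls; AREG averaged 112 and 5.71 CPM.

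Among components of the PDGF receptor, SHP2 and RAS pathway, the kinase ERK1 (MAPK3) fell from 74.8 ± 3.47 to 49.0 ± 2.19 CPM (log2 fold change −0.61, SE 0.08) and the RAS GTPase-activating protein RASA1 from 121 ± 24.0 to 71.4 ± 6.02 CPM (−0.76). The SHP2-binding adaptor GAB1 rose from 20.4 ± 3.16 to 32.2 ± 0.526 CPM (0.66). Of 21 tested members, 1 rose, 2 fell and 18 did not pass. Counts adjusted over the list alone were 3 higher and 4 lower, and the list as a set did not differ from other genes (camera adjusted p = 0.514). With the block, 3 members were higher and 5 lower, among the higher the PDGF receptor beta gene PDGFRB (271 ± 45.7 and 376 ± 5.34 CPM; 0.47, SE 0.13), whose adjusted p was 0.0867 without and 0.0301 with it. The receptor gene PDGFRA averaged 1136 ± 313 and 858 ± 79.0 CPM (−0.41, adjusted p = 0.268). Among genes whose transcription ERK signalling drives, the early growth response gene EGR3 fell from 6.49 ± 1.66 to 1.201 ± 0.743 CPM (−2.43, SE 0.43), while the ERK phosphatase DUSP5 rose (0.88, SE 0.14) and so did the chromatin protein HMGA2 (0.65). Of 26 members, 2 rose, 1 fell and 23 did not pass. The counts were also 2 and 1 adjusted over the list alone, and 2 and 4 with the block. The set had a median log2 fold change of −0.29 (camera adjusted p = 0.301), with 0.15, −0.44 and −0.54 in the 3 same-numbered pairs and −0.13 to −0.53 when a library was left out. It passed as lower without PDGF replicate 1 (adjusted p = 0.0219) and with replicates 2 and 3 alone (0.00647, 5 members higher and 17 lower), but did not in all libraries with an estimated correlation (0.679). Among receptor tyrosine kinases and their ligands, AREG (−4.29), EREG (−2.86) and the hepatocyte growth factor gene HGF (−1.07) fell and the stem cell factor receptor KIT rose (1.85). In all 1 of 37 rose, 3 fell and 33 did not pass. Counts adjusted over the list alone were 3 higher and 5 lower. The median was 0.23 but the mean −0.09, and the set did not pass (camera adjusted p = 0.913). The direction of its test was not stable: it pointed up in the first fit and down with fry, with library size alone, and without PDGF replicate 2, SHP099 replicate 2 or SHP099 replicate 3. The median was 0.05 without PDGF replicate 2 and 0.09 without SHP099 replicate 1. With the block 5 were higher and 9 lower. With the GC correction GAB1 went from 0.66 (SE 0.12) to 0.51 (SE 0.12, adjusted p = 0.0760) and HMGA2 from 0.65 (SE 0.14) to 0.52 (SE 0.16, adjusted p = 0.126), and both lost their calls through smaller folds, HMGA2 also through a larger SE. HGF went from −1.07 (SE 0.24) to −1.22 (SE 0.26, adjusted p = 0.0570) and KIT from 1.85 (SE 0.39) to 1.75 (SE 0.37, adjusted p = 0.0555), and lost theirs through the stricter limit on p. HMGA2 also lost its call with the GC correction and the block (0.51, SE 0.17, adjusted p = 0.122), and MAPK3 kept its call with the GC correction at a smaller fold (−0.40, adjusted p = 0.0336). Without PDGF replicate 2, PDGF replicate 3, SHP099 replicate 2 or SHP099 replicate 3, no member of the first 2 lists passed in edgeR, while 7 or 8 and 5 or 6 of their members had an unadjusted p under 0.05; of the receptors and ligands 2, 2, 2 and 1 passed, all lower. Without PDGF replicate 1 the 3 lists had 2 higher and 5 lower, 3 and 8, and 4 and 8; without SHP099 replicate 1 they had 1 and 2, 1 and 3, and 4 and 3.

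Interferon-stimulated genes were the group with the most members that rose: 24 of 36, with 0 lower and 12 that did not pass. Adjusted over the list alone, 34 were higher and 0 lower. The antiviral protein viperin (RSAD2) rose from 0.434 ± 0.0286 to 3.69 ± 0.665 CPM (log2 fold change 3.08, SE 0.21, adjusted p = 0.00305), OAS2 from 1.84 ± 0.380 to 14.2 ± 3.42 CPM (2.94, SE 0.24), and the virus-tethering protein BST2 from 2.03 ± 0.628 to 12.8 ± 2.29 CPM (2.65, SE 0.25). The list's median log2 fold change was 1.71, and it was 1.40, 1.62 and 1.98 in the 3 same-numbered pairs (camera adjusted p = 1.05e-21; adjusted p = 0.241 with an estimated correlation). The number that rose was 8 without PDGF replicate 2, 7 without PDGF replicate 3, 13 without SHP099 replicate 2 and 5 without SHP099 replicate 3, with 0 lower each time, and 34 were higher with the block. Inflammatory cytokines and chemokines had a median log2 fold change of 1.996, with 6 of 34 higher, 0 lower and 28 that did not pass. Without SHP099 replicate 1 the median was 1.09, with 7 higher and 1 lower, and without each of the others it lay between 1.79 and 2.60. Adjusted over the list alone, 21 were higher and 1 lower. The macrophage growth factor CSF1 rose from 62.2 ± 6.63 to 130 ± 22.8 CPM (1.07, SE 0.15), the cytokine IL32 from 11.2 ± 3.32 to 40.3 ± 15.02 CPM (1.84, SE 0.31) and the adhesion molecule VCAM1 from 94.8 ± 21.0 to 179 ± 15.5 CPM (0.92, SE 0.16). The set passed as higher (camera adjusted p = 1.87e-10; adjusted p = 0.535 with an estimated correlation), and its directional fry test did not (adjusted p = 0.0906). With the block 27 were higher and 1 lower. The count was 15 without PDGF replicate 1 and 0 without PDGF replicate 2, PDGF replicate 3, SHP099 replicate 2 or SHP099 replicate 3, where 18, 17, 27 and 28 members had an unadjusted p under 0.05 in edgeR. VCAM1 went with the GC correction from 0.92 (SE 0.16) to 0.74 (SE 0.16, adjusted p = 0.0530) and lost its call through a smaller fold and the stricter limit on p, and 4 of the list were higher. The list also differed between replicates: 28 of its members were higher and 0 lower in replicate 1 than in replicates 2 and 3.

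**Figure D3:**
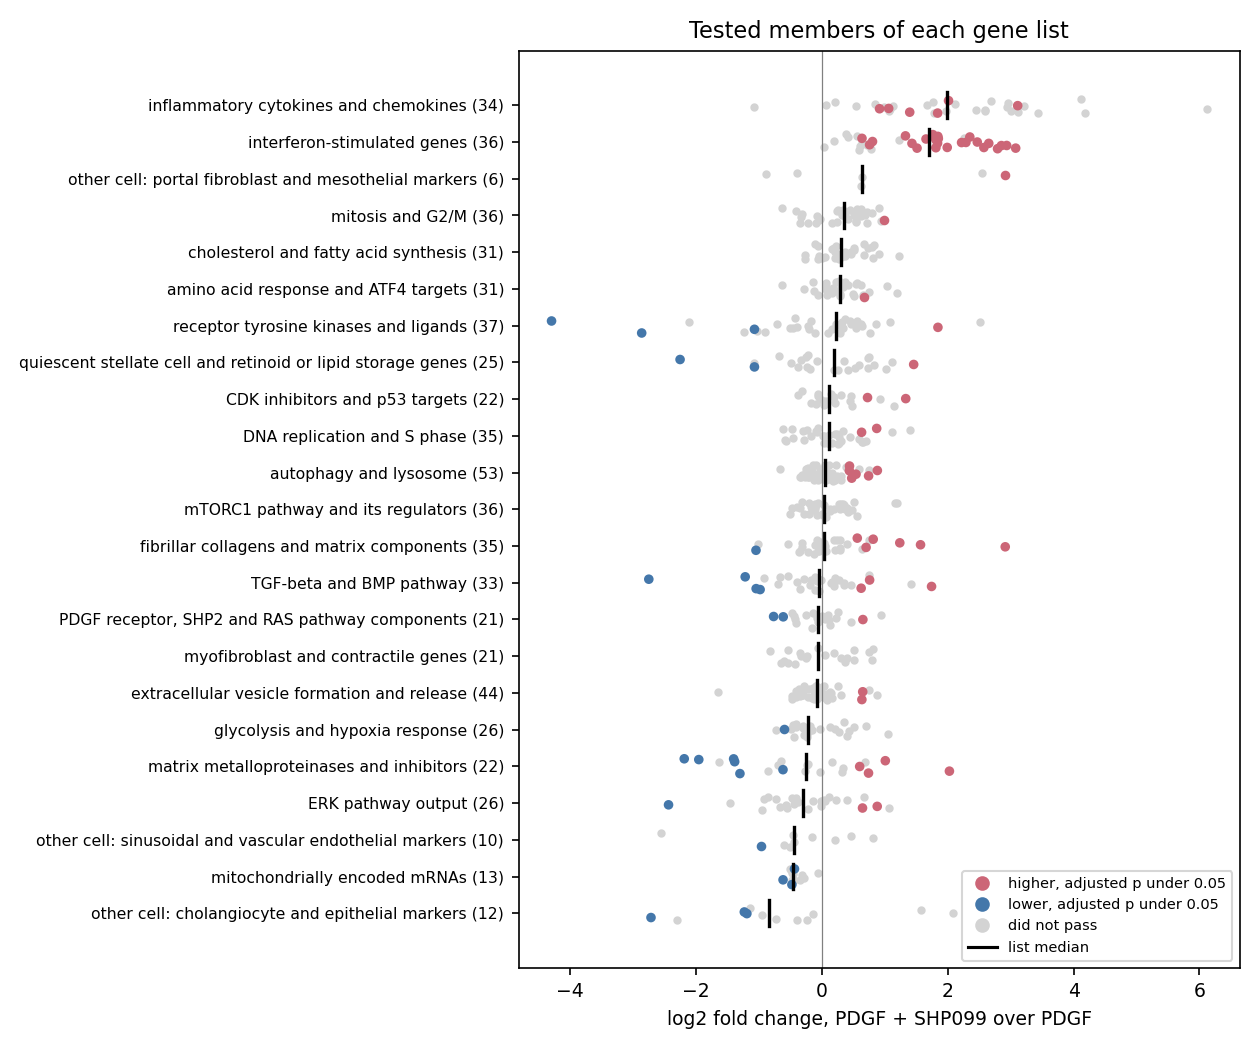
Log2 fold change (SHP099 with PDGF over PDGF) of each tested member of the 23 lists with at least 5 tested members, whose numbers stand in brackets; red and blue points passed as higher or lower, grey points did not pass, and black bars are list medians. The inflammatory and interferon lists have the highest medians (1.996 and 1.71), and the cholangiocyte markers the lowest (−0.84).

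Few cell cycle genes passed. Of 35 tested genes of DNA replication, 2 rose, 0 fell and 33 did not pass: the ribonucleotide reductase subunit RRM2 (1.96 ± 0.216 to 3.59 ± 0.545 CPM; log2 fold change 0.88) and the DNA polymerase alpha subunit POLA1 (0.64). The count adjusted over the list alone was 3 higher and 1 lower (camera adjusted p = 0.276), and with the block 3 were higher and 3 lower. Of 36 mitotic genes, the kinetochore gene NDC80 rose (0.541 ± 0.0242 to 1.08 ± 0.0801 CPM; 1.00), 0 fell and 35 did not pass. Adjusted over the list alone 0 passed in edgeR, with 9 higher and 1 lower at an unadjusted p under 0.05. DESeq2 called 6 higher and 1 lower over all genes, and limma-voom 1 and 0. The set passed as higher with a median of 0.35 (camera adjusted p = 7.20e-04; adjusted p = 0.241 with an estimated correlation). It did not pass with replicates 2 and 3 alone (0.0588), and with the block 4 were higher and 2 lower. Of 22 CDK inhibitors and p53 targets, 2 rose, 0 fell and 20 did not pass: the proapoptotic gene BBC3 (30.8 ± 3.38 to 51.0 ± 5.42 CPM; 0.73, SE 0.12) and the CDK inhibitor CDKN1C (7.63 ± 2.96 to 19.3 ± 0.221 CPM; 1.34, SE 0.25). Adjusted over the list alone 7 were higher and 0 lower. The set passed as higher (camera adjusted p = 0.0232; adjusted p = 0.241 with an estimated correlation). It did not pass without PDGF replicate 1 (0.129), with replicates 2 and 3 alone (0.143) or with the block (0.0510, 7 higher and 1 lower). With the GC correction RRM2 went from 0.88 (SE 0.18) to 0.83 (SE 0.19, adjusted p = 0.0651) and NDC80 from 1.00 (SE 0.20) to 0.87 (SE 0.20, adjusted p = 0.0656), and both lost their calls through smaller folds, RRM2 also through a larger SE. NDC80 did not pass with the GC correction and the block either (0.87, SE 0.22, adjusted p = 0.0522). POLA1 went from 0.64 (SE 0.14) to 0.54 (SE 0.12, adjusted p = 0.0574) and lost its call through the stricter limit on p. Without PDGF replicate 2, PDGF replicate 3, SHP099 replicate 2 or SHP099 replicate 3, no member of the 3 lists passed in edgeR, while 7 to 11 members of each had an unadjusted p under 0.05. Without PDGF replicate 1 the replication list had 5 higher and 1 lower, the mitotic list 2 and 1, and the last list 4 and 0; without SHP099 replicate 1 the counts were 1 and 0, 0 and 0, and 3 and 0.

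Matrix genes changed in both directions. ELN rose from 3.24 ± 1.45 to 24.5 ± 2.62 CPM (log2 fold change 2.92, SE 0.31), the collagen-binding proteoglycan lumican (LUM) from 111 ± 12.6 to 331 ± 47.8 CPM (1.57, SE 0.14) and the crosslinking enzyme LOX from 320 ± 12.9 to 564 ± 35.4 CPM (0.82, SE 0.09), while the prolyl hydroxylase subunit P4HA3 fell from 60.6 ± 4.47 to 29.4 ± 1.82 CPM (−1.04, SE 0.09). Of 35 collagens and matrix components 6 rose, 1 fell and 28 did not pass. Counts adjusted over the list alone were 6 higher and 2 lower (camera adjusted p = 0.325; fry adjusted p = 0.0241; adjusted p = 0.535 with an estimated correlation), and with the block 10 were higher and 3 lower. Of 22 matrix metalloproteinases and inhibitors 4 rose, 6 fell and 12 did not pass. Both adjusted over the list alone and with the block, 6 were higher and 7 lower (camera adjusted p = 0.303). The protease ADAMTS1 fell from 739 ± 39.1 to 163 ± 59.7 CPM (−2.18, SE 0.28), stromelysin 2 (MMP10) from 8.46 ± 0.404 to 2.19 ± 0.563 CPM (−1.95, SE 0.20) and MMP16 from 17.3 ± 4.09 to 6.59 ± 0.999 CPM (−1.40), while the membrane collagenase MMP14 rose from 1340 ± 92.6 to 2702 ± 356 CPM (1.01, SE 0.13). Of 21 contractile genes 0 passed in edgeR, with 0 higher and 3 lower at an unadjusted p under 0.05, and adjusted over the list alone 0 passed as well. DESeq2 called 1 lower and limma-voom 0 (camera adjusted p = 0.872). The list median was −0.06 and lay between −0.25 and 0.17 when a library was left out, so it had no stable direction. The smallest p was that of tropomyosin 2 (TPM2; 942 ± 117 and 603 ± 90.8 CPM, −0.64), with an adjusted p of 0.0568 without and 0.00395 with the block, which called 2 contractile genes higher and 5 lower. Without PDGF replicate 2, PDGF replicate 3, SHP099 replicate 2 and SHP099 replicate 3 in turn, the matrix list had 2, 2, 3 and 2 higher with 1 lower each, and the protease list 0, 0, 0 and 1 higher and 1, 1, 1 and 0 lower. Without PDGF replicate 1 the matrix list had 8 higher and 4 lower, the protease list 6 and 6, and the contractile list 0 and 4; without SHP099 replicate 1 the protease list had 4 higher and 9 lower and the contractile list 1 and 0.

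Among genes of quiescent, retinoid-storing stellate cells, the adipogenesis factor ADIRF fell from 15.4 ± 1.77 to 3.23 ± 0.827 CPM (log2 fold change −2.25, SE 0.20), a value shared with its antisense gene over 91.9% of its exons. HGF fell from 412 ± 103 to 197 ± 50.9 CPM (−1.07), and the chemoattractant gene RARRES2 rose from 23.0 ± 5.36 to 63.5 ± 4.14 CPM (1.46, SE 0.17). Of 25 members 1 rose, 2 fell and 22 did not pass. Counts adjusted over the list alone were 2 higher and 3 lower (camera adjusted p = 0.671), and with the block 5 and 4. In the TGF-beta and BMP pathway the BMP-induced transcription regulators ID2 (26.8 ± 1.04 to 13.6 ± 0.456 CPM; −0.98, SE 0.09) and ID3 (47.0 ± 3.94 to 20.3 ± 2.71 CPM; −1.21, SE 0.12) fell, as did the ligand BMP2 (50.3 ± 3.73 to 24.5 ± 4.65 CPM; −1.04), while the receptor TGFBR1 rose (74.0 ± 4.31 to 125 ± 5.77 CPM; 0.76). Of 33 members 3 rose, 4 fell and 26 did not pass. Counts adjusted over the list alone were 4 higher and 6 lower (camera adjusted p = 0.514), and with the block 6 and 6. HGF did not pass with the GC correction (log2 fold change −1.07, SE 0.24, before and −1.22, SE 0.26, adjusted p = 0.0570, after, through the stricter limit on p) or with library size alone, without a filter or at an average CPM of at least 1. Without PDGF replicate 2, PDGF replicate 3, SHP099 replicate 2 and SHP099 replicate 3 in turn, the quiescence list had 1, 0, 1 and 0 higher and 1 lower each time, and the TGF-beta and BMP list 0, 0, 1 and 0 higher and 2, 2, 2 and 1 lower. Without PDGF replicate 1 the counts were 5 higher and 3 lower and 7 higher and 6 lower; without SHP099 replicate 1 they were 2 and 2, and 3 and 5.

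In metabolism, 3 of 13 messenger RNAs encoded in the mitochondrial genome, which specify subunits of the respiratory chain, fell with SHP099, 0 rose and 10 did not pass. MT-ATP6 fell from 2217 ± 91.1 to 1451 ± 163 CPM (log2 fold change −0.61, SE 0.12), MT-CO2 from 2145 ± 12.9 to 1547 ± 104 CPM (−0.47) and MT-CO3 from 2716 ± 94.6 to 2016 ± 37.6 CPM (−0.43). In the count adjusted over the list alone 11 were lower and 0 higher. The set passed as lower (camera adjusted p = 6.96e-07; adjusted p = 0.510 with an estimated correlation), and with the block 10 members were lower. The mitochondrial share of all counts was 2.98% ± 0.138 with PDGF and 2.36% ± 0.153 with SHP099 (SD, n = 3; two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries can give). With the GC correction MT-CO2 went from −0.47 (SE 0.10) to −0.51 (SE 0.11, adjusted p = 0.0533) and lost its call through the stricter limit on p. MT-CO2 and MT-CO3 lost theirs with library size alone. Of 31 genes of cholesterol and fatty acid synthesis 0 passed in edgeR and 0 adjusted over the list alone, with 2 higher and 0 lower at an unadjusted p under 0.05. DESeq2 called 1 higher and limma-voom 0. The smallest p was that of lanosterol synthase (LSS; 370 ± 144 and 660 ± 69.8 CPM; 0.84, adjusted p = 0.154), which passed with replicates 2 and 3 alone at a smaller fold (0.45, adjusted p = 6.75e-06). The set passed as higher (camera adjusted p = 0.0172; adjusted p = 0.679 with an estimated correlation), with medians of 1.68, 0.06 and 0.02 in the 3 same-numbered pairs. It did not pass, and its direction turned, without PDGF replicate 1 (0.547), with a median of −0.06 against 0.31 in all libraries. It also did not pass without SHP099 replicate 2 (0.0873) or SHP099 replicate 3 (0.0700), with replicates 2 and 3 alone (0.495) or with fry (0.496). Of 31 targets of the amino acid response factor ATF4, the stress factor ATF3 rose (10.1 ± 1.00 to 16.1 ± 1.39 CPM; 0.68), 0 fell and 30 did not pass. The count adjusted over the list alone was 1 higher and 0 lower. As a set they passed as higher (camera adjusted p = 0.0232; adjusted p = 0.679 with an estimated correlation), but did not without PDGF replicate 1 (0.920), SHP099 replicate 2 (0.158) or SHP099 replicate 3 (0.125), or with fry (0.458). With replicates 2 and 3 alone they passed as higher (0.0311, 16 members higher and 5 lower). Their median was 0.29, and −0.06 without PDGF replicate 1. With the block 7 members were higher and 1 lower. In a term that averages both groups, 7 cholesterol genes and 23 ATF4 targets were lower in replicate 1 than in replicates 2 and 3, and 0 of either list higher. The pair medians of the cholesterol list differ, so its replicate 1 difference was not the same in both groups. Pair medians of the ATF4 list were 0.74, 0.16 and 0.21, so its replicate 1 difference also varied between the groups, to a lesser degree. LSS had 204 CPM in PDGF replicate 1 against 459 and 447 in replicates 2 and 3, but 740 against 633 and 608 with SHP099. Of 26 glycolytic and hypoxia genes the glycolytic enzyme GAPDH fell (2885 ± 387 to 1912 ± 86.9 CPM; −0.59), 0 rose and 25 did not pass. In the count adjusted over the list alone 4 were higher and 6 lower (camera adjusted p = 0.276), and with the block 3 and 6. With the GC correction GAPDH went from −0.59 (SE 0.13) to −0.43 (SE 0.13, adjusted p = 0.120) and lost its call through a smaller fold. Without PDGF replicate 2, PDGF replicate 3, SHP099 replicate 2 or SHP099 replicate 3, no member of these 4 lists passed in edgeR. An unadjusted p under 0.05 was then held by 9 or 10 mitochondrial, 8 to 10 glycolytic, 0 to 2 cholesterol and 2 to 5 ATF4 members. Without PDGF replicate 1 the mitochondrial list had 5 lower, the cholesterol list 3 higher, the ATF4 list 3 higher and 1 lower and the glycolytic list 2 higher and 10 lower; without SHP099 replicate 1 the mitochondrial list had 5 lower, the ATF4 list 2 higher and the glycolytic list 3 lower.

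Of 53 genes of autophagy and the lysosome 6 rose, 0 fell and 47 did not pass. The cholesterol carrier NPC2 rose from 116 ± 5.89 to 195 ± 19.1 CPM (log2 fold change 0.75, SE 0.10), the autophagosome protein GABARAPL1 from 122 ± 21.8 to 225 ± 40.5 CPM (0.89) and the conjugation enzyme ATG7 from 43.0 ± 2.01 to 62.8 ± 9.07 CPM (0.55). The count adjusted over the list alone was 8 higher and 0 lower (camera adjusted p = 0.276), and with the block 12 and 2. In the mTORC1 pathway 0 of 36 passed in edgeR, with 9 higher and 5 lower at an unadjusted p under 0.05. The count adjusted over the list alone was 5 higher and 4 lower. DESeq2 called 4 and 4, and limma-voom 0 (camera adjusted p = 0.514). The mTORC1 inhibitor DDIT4 averaged 95.9 ± 39.2 CPM with PDGF and 215 ± 47.7 with SHP099 (1.16, SE 0.34), with an adjusted p of 0.0991 without and 0.00624 with the block; an overlapping gene covers 41.2% of its exons. The folliculin partner FNIP1 (0.36) had the smallest p, with adjusted p values of 0.0501 without and 0.0147 with the block, and of 0.0678 with the block and the GC correction. With the block 9 members were higher and 4 lower. Of 44 genes of extracellular vesicle formation and release, the exosome-docking GTPase RAB27B (10.2 ± 0.570 to 15.9 ± 1.09 CPM; 0.64) and the adaptor syntenin (SDCBP; 234 ± 31.2 to 367 ± 41.7 CPM; 0.65) rose, 0 fell and 42 did not pass. Adjusted over the list alone 4 were higher and 4 lower (camera adjusted p = 0.367), and with the block 6 and 7. The kinase ROCK1 averaged 103 ± 5.65 and 95.0 ± 8.75 CPM (−0.12, SE 0.10, adjusted p = 0.519). With the block alone it was also at −0.12 (adjusted p = 0.249), and with the block and the GC correction the fold was larger and passed (−0.25, SE 0.06, adjusted p = 0.0443). SDCBP went with the GC correction from 0.65 (SE 0.13) to 0.52 (SE 0.15, adjusted p = 0.116) and lost its call through a smaller fold and a larger SE. GABARAPL1 went from 0.89 (SE 0.17) to 0.86 (SE 0.19, adjusted p = 0.0596) and RAB27B from 0.64 (SE 0.10) to 0.47 (SE 0.10, adjusted p = 0.0513). These 2 lost theirs through the stricter limit on p together with a larger SE for GABARAPL1 and a smaller fold for RAB27B. Without PDGF replicate 2, PDGF replicate 3, SHP099 replicate 2 or SHP099 replicate 3, no member of these 3 lists passed in edgeR, while 8 to 12 members of each had an unadjusted p under 0.05. Without PDGF replicate 1 the counts were 9 higher and 2 lower, 3 and 1, and 3 and 7; without SHP099 replicate 1 they were 3 and 3, 2 and 2, and 2 and 2.

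Most markers of other liver cells were below 1 CPM, but some were abundant. The highest level in any library was 166 CPM among portal fibroblast markers (THY1) and 115 among endothelial markers (TEK). It was 79.5 CPM among cholangiocyte (SOX9), 53.5 among macrophage (CD68), 44.1 among lymphocyte (CD4) and 3.40 among hepatocyte markers (ASGR1). Under 1 CPM in every library were 17 of 19 hepatocyte, 17 of 18 macrophage, 13 of 15 lymphocyte, 12 of 19 endothelial, 8 of 14 portal fibroblast and 4 of 14 cholangiocyte and epithelial markers. Of the last, which stellate cells can share, the transcription factor SOX9 fell from 75.6 ± 10.0 to 32.3 ± 4.09 CPM (log2 fold change −1.23, SE 0.14), the mucin MUC1 from 10.1 ± 0.522 to 4.44 ± 0.374 CPM (−1.19, SE 0.12) and the keratin KRT19 from 10.95 ± 4.65 to 1.67 ± 0.344 CPM (−2.71, SE 0.37). Of 12 tested 0 rose, 3 fell and 9 did not pass. In the count adjusted over the list alone 6 were lower and 0 higher, and with the block 4 were lower and 1 higher. As a set they passed as lower with a median of −0.84 (camera adjusted p = 0.00113; adjusted p = 0.241 with an estimated correlation). Of 10 endothelial markers the secreted protein EGFL7 fell (5.02 ± 0.0822 to 2.57 ± 0.331 CPM; −0.97), 0 rose and 9 did not pass. In the count adjusted over the list alone 2 were lower and 0 higher (camera adjusted p = 0.133; fry adjusted p = 0.0196; adjusted p = 0.510 with an estimated correlation), and with the block 2. The set passed as lower at an average CPM of at least 1 (camera adjusted p = 0.0276). Of 6 portal fibroblast markers ELN rose, 0 fell and 5 did not pass. The count adjusted over the list alone was 2 higher and 1 lower (camera adjusted p = 0.276), and with the block 2 and 2. Of 3 macrophage markers tested, CD68, a lysosomal protein that other cells also make, fell from 52.5 ± 0.167 to 31.9 ± 7.03 CPM (−0.72). This value is shared over 81.7% of the CD68 exons with a gene on the same strand, ENSG00000264772. That gene is listed as SNORA67, a symbol carried by more than 1 gene. For this list the count adjusted over the list alone was 1 higher and 1 lower, with a median of −0.30 and a mean of 0.18. Of 4 hepatocyte and 2 lymphocyte markers 0 passed in edgeR, DESeq2 or limma-voom, 0 had an unadjusted p under 0.05, and 0 passed adjusted over the list alone; the receptor gene ASGR1 (2.95 ± 0.361 and 2.102 ± 0.501 CPM) and KLRD1 (0.217 ± 0.0452 and 0.542 ± 0.412 CPM) had the smallest p. ASGR1 passed as lower with replicates 2 and 3 alone (−0.61, adjusted p = 0.0140). With the block 1 lymphocyte marker was lower. With the GC correction CD68 went from −0.72 (SE 0.15) to −0.63 (SE 0.13, adjusted p = 0.0533) and lost its call through the stricter limit on p. It also lost it without PDGF replicate 2, PDGF replicate 3, SHP099 replicate 2 or SHP099 replicate 3 (adjusted p up to 0.172), and so did EGFL7 without these libraries (up to 0.107). Cholangiocyte markers that fell numbered 5 without PDGF replicate 1, 2, 2 and 2 without PDGF replicate 2, PDGF replicate 3 and SHP099 replicate 2, and 1 without SHP099 replicate 3.

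The authors' deposited table gave a false discovery rate under 0.05 to 1454 genes, 726 higher and 728 lower with SHP099. Of 20072 genes present in both, 1305 passed in the authors' deposited table and 1207 in the edgeR fit above, and the 964 that passed in both had the same direction. The log2 fold changes of the authors' deposited table and of the fit had a Spearman correlation of 0.99998 across genes and a median absolute difference of 0.0027. Both come from the same libraries, and the submitters also list edgeR. Close fold changes were therefore bound to arise and are no independent check of the results.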

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

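The fits with replicates 2 and 3 alone, with a term for replicate 1 and with the GC correction were chosen after seeing the data; all other settings were planned, and none turned the direction of a named gene that passed. The main count of 1252 genes (572 higher, 680 lower) was within 1.5 times with DESeq2's size factors, upper-quartile scaling, library size alone, no filter, an average CPM of at least 1 and limma-voom (1198 to 1381). With DESeq2 the counts changed, higher and lower were 2837, 1349 and 1488; with the replicate block 3753, 1719 and 2034, including 1244 of the main calls; with replicates 2 and 3 alone 8624, 4148 and 4476; with a term for replicate 1 5391, 2519 and 2872; with the GC correction 794, 417 and 377; with the replicate block and GC correction 2897, 1500 and 1397; with glmTreat 128, 54 and 74; and at an adjusted p under 0.01 166, 74 and 92. Leaving out a library gave from 85, 43 and 42 (without SHP099 replicate 3) to 2661, 1181 and 1480 (without PDGF replicate 1). By construction, fewer libraries remove degrees of freedom and the block removes the spread between replicate numbers. Lost degrees of freedom cannot account for the rise to 2661 without PDGF replicate 1 and to 1766 without SHP099 replicate 1. Those libraries differed most from the others of their group (chi-square per degree of freedom 171 and 163, and 142 and 112, against 5.12 and 10.3 between replicates 2 and 3). Other causes were not tested. Among the lists, the adjusted p with an estimated correlation was 0.241 for interferon genes, mitosis, CDK inhibitors and cholangiocyte markers, 0.535 for inflammatory genes, 0.510 for mitochondrial mRNAs and 0.679 for cholesterol genes and ATF4 targets, so no list call held with it. That form of the test rests on the few residual degrees of freedom of 6 libraries. The estimated correlation was −0.016 for CDK inhibitors and −0.048 for cholangiocyte markers, below the preset 0.01, so correlation does not account for those losses. It was above the preset for the other lists with calls: 0.405 for interferon genes, 0.0277 for mitosis and 0.79985 for inflammatory genes. For mitochondrial mRNAs it was 0.671, for cholesterol genes 0.943 and for ATF4 targets 0.697. In these lists the preset may be too low and the main camera p too small. Correlation is therefore not excluded as a reason for their losses. With fry the adjusted p was 0.00948 for interferon genes and CDK inhibitors, 0.0130 for mitosis, 0.0196 for mitochondrial mRNAs and 0.00469 for cholangiocyte markers. It was 0.0906 for inflammatory genes, 0.496 for cholesterol genes, 0.458 for ATF4 targets and 0.0241 for the matrix list (0.535 with an estimated correlation). With replicates 2 and 3 alone it was 0.00647 for ERK output, 0.0588 for mitosis, 0.143 for CDK inhibitors, 0.495 for cholesterol genes and 0.0311 for glycolysis, while ERK output and glycolysis had 0.679 in all libraries with an estimated correlation. The matrix list passed with the replicate block and GC correction (0.0486), and endothelial markers at an average CPM of at least 1 (0.0276) and with fry (0.0196). Endothelial markers had 0.510 in all libraries with an estimated correlation. Leaving out a library gave 0.0219 to 0.496 for ERK output, 0.0137 to 0.129 for CDK inhibitors, 5.19e-05 to 0.547 for cholesterol genes and 4.26e-04 to 0.920 for ATF4 targets. With the replicate block, the CDK inhibitor list did not pass (0.0510), and PDGFRB, DDIT4, TPM2 and FNIP1 did; it changed no other call of a list or named gene. DESeq2 called PDGFRB, DDIT4, TPM2, FNIP1 and LSS, and replicates 2 and 3 alone called these and ACTA2 and ASGR1; ROCK1 passed only with the replicate block and GC correction. Over the settings followed, which leave out glmTreat, list tests kept their side of the threshold 430 times, lost a call 22 times and gained one 7 times. Named genes did so 1102, 214 and 32 times. Depth limits genes below 0.0441 to 0.0578 CPM, the level of 3 counts, and the filter on low counts left some genes above that level untested. The simulated test with the replicate effects of these libraries recovered 41.8% of 2-fold changes. It changed only 200 genes, against 1252 called in the data, so the share in the data may differ. A gene that did not pass may still have changed.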

Other observations

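Of the tests in this part, the count over splits of the libraries, the GC trend of genes that are not protein coding and the GC correction of the replicate difference were set before their results were seen; the others were chosen afterwards, as were the genes named in the next paragraph.

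MTSS1, which encodes an actin- and membrane-binding scaffold, rose: 9.45 ± 0.151 CPM with PDGF and 59.8 ± 5.05 with SHP099 (log2 fold change 2.66, SE 0.10, edgeR adjusted p = 3.5e-04, higher in all 3 SHP099 libraries than in any PDGF library). LRRN4CL rose from 4.75 ± 0.178 to 20.4 ± 0.452 CPM (2.11, SE 0.09), and the secreted WNT antagonist SFRP1 fell from 788 ± 28.9 to 190 ± 29.2 CPM (−2.05, SE 0.13). The metalloproteinase inhibitor TIMP1 fell from 1547 ± 297 to 630 ± 169 CPM (−1.30, SE 0.22, edgeR adjusted p = 0.0246). The cytokine genes CXCL8 (93.3 ± 45.0 and 862 ± 858 CPM; 3.21, SE 0.76) and IL6 (6.53 ± 4.85 and 119 ± 150 CPM; 4.19, SE 1.10) had large but variable differences that did not pass (edgeR adjusted p = 0.0589 and 0.0753) without the block (2.85 and 3.64, adjusted p = 0.00988 and 0.0107, with it).

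Replicate 1 differed from replicates 2 and 3 by named groups of genes, with treatment in the model. Higher in replicate 1 were the prostaglandin synthase PTGS2 (log2 difference 2.58, SE 0.12), the chemokines CXCL6 (2.38), CXCL5 (2.102) and CCL2 (1.96), the hyaluronan-binding TNFAIP6 (1.81) and the serpins SERPINB10 (2.56) and SERPINB2 (2.53). Of the inflammatory list 28 of 34 were higher and 0 lower (camera adjusted p = 1.46e-17; adjusted p = 0.468 with an estimated correlation). Of contractile genes 1 was higher and 15 lower (1.17e-08 and 0.468), of ATF4 targets 0 and 23 (3.83e-11 and 0.807), of cholesterol genes 0 and 7 (4.74e-09 and 0.807) and of interferon genes 11 and 2 (0.00924 and 0.969). The term averages both groups. Cholesterol genes had median log2 differences of 1.68, 0.06 and 0.02 in same-numbered pairs, so their replicate 1 difference was not the same in both groups. For ATF4 targets these were 0.74, 0.16 and 0.21, so the same holds for them to a lesser degree.

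The count of 1252 changed genes was set against the other splits of the 6 libraries into 3 and 3. Only 1 of the 10 splits, the real one, gave as many; the highest of the others was 0 in edgeR and in limma-voom and 148 in DESeq2, with 87 to 2273 genes at an unadjusted p under 0.05. Of the 4 splits that part all 3 pairs, the real one gave 3753 genes with the block and the other 3 gave 0. With 10 splits the share cannot go below 0.1, so the splits are too few to exclude chance.

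Of 36 interferon-stimulated genes 24 rose with SHP099 and of 34 inflammatory genes 6, but as sets neither passed with an estimated correlation (adjusted p = 0.241 and 0.535), and the inflammatory set did not with fry (0.0906). The interferon set did pass with fry (adjusted p = 0.00948). The GC trend is argued against for most of these calls: the GC correction took the interferon genes that were higher from 24 to 20 and the inflammatory genes from 6 to 4, and with the replicate block from 34 to 33 and from 27 to 26, with an interferon median of 1.69. A large share of immune cells in the cultures is argued against by their own transcripts. The highest SHP099 mean among 8 abundant transcripts of macrophages and leukocytes was 0.551 CPM, for FCER1G, which averaged 0.182 CPM with PDGF. PTPRC, also among the 8, averaged 0.0108 CPM with PDGF and 0.0106 with SHP099. These levels do not exclude a few such cells. Without both replicate 1 libraries the interferon median was 1.80, so those libraries alone do not account for the interferon change. An effect of SHP099 on these cells stays open as a hypothesis and was not tested otherwise.

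Fold changes fell with GC content, from a median log2 fold change of 0.14 in the fifth of genes with the lowest GC percent to −0.22 in the fifth with the highest. Library size is argued against, since the correlation was −0.45 in the pair whose SHP099 library was the larger. A bias of the libraries shared by all transcript classes may contribute: genes that are not protein coding had a correlation of −0.32, and libraries of the same group differed along GC as well, by up to 0.35. A change of GC-rich transcripts with SHP099 stays open and was not tested.

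Replicate 1 of both groups stood apart from replicates 2 and 3. Library size is argued against, since the larger replicate 1 total, 64.1 M counts, lies within the range of the others, 51.9 to 67.97 M. The GC trend is argued against by 4685 genes that differed with the GC correction, against 4712 without. A large share of immune cells is argued against by a highest replicate 1 mean of 0.521 CPM, for FCER1G, among the same 8 transcripts. A few such cells are not excluded. CD68 and CD4, not among the 8, averaged 47.0 and 26.9 CPM in replicate 1. A separate culture, passage or day may lie behind it, but the labels name none, and no other explanation was tested.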
